A study of Mus musculus with 72 samples.

How the data were processed

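The series holds 72 RNA-seq libraries of mouse neural progenitor cells, 10 from founder strains and 62 from Diversity Outbred lines, with 1 table per library. Per the labels' protocols, total RNA underwent polyA selection and stranded mRNA library preparation and was sequenced as paired ends, while the sample descriptions call the libraries ribodepleted. The authors quantified transcripts with Salmon and name DESeq2 and the genome build mm10, with no versions given. The expected counts in the deposited tables are estimated fragments per transcript and need not be whole numbers. The TPM in the deposited tables (transcripts per 1e+06) were not used in any test. The effective length in the deposited tables is the transcript length adjusted for the fragment sizes of the library, in bases, and was used for length offsets alone. Series text also names epiblast stem cell and definitive endoderm samples, which were not analysed here.

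Founder tables list 116224 transcripts, and 117135 are in those of the outbred lines, with 115622 shared and 115212 of these of the same length. Of these transcripts 114857 and 115973 were found in GENCODE M21 on GRCm38, which gave gene symbols and coordinates, and 0.374 to 0.673% of a library's counts had no match. Transcript versions matched that release for 0.0112% of founder transcripts and 98.5% of outbred transcripts, so the kinds of line were quantified against different annotations. Counts were summed to genes (35308 in founders, 35523 in outbred lines, 35197 in both, 34456 with identical models) and rounded. The printed levels in counts per 1e+06 counts (CPM), and the CPM of the count filter, used plain library totals. Scaling of library sizes by TMM entered the edgeR and camera tests.

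Differential tests used edgeR 4.0.16 (quasi-likelihood, TMM) in R 4.3.3, with adjusted p by Benjamini-Hochberg and a threshold of 0.05. Genes needed 0.5 CPM in at least 2 founder libraries, or in at least 10 libraries where outbred lines were included. The founder fit had 1 mean per strain and gave an F-test and contrasts of each strain with C57BL/6J; the lone NOD/ShiLtJ and WSB/EiJ lines were assumed to vary like the other strains. The 5 contrasts share their C57BL/6J libraries, so their results were not compared with each other. A second fit compared 62 outbred with 10 founder libraries, and another the 6 title series. Founder similarity was tested by permuting strain labels over 10 libraries (100000 permutations and exact enumeration). Spread was the ratio of edgeR's common coefficients of variation. The variability of genes was compared as the Spearman correlation across genes of SDs, each taken as residual from its trend with the mean. Chromosome shifts were medians over genes of log2 CPM less the gene's median over all 72 libraries, read against 0.3.

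The 17 gene lists, fixed with the tests, groups, named-gene rule and alternatives before the data were examined, were pan-neural progenitor; telencephalon and anterior forebrain; dorsal telencephalon; ventral telencephalon; midbrain, hindbrain and spinal cord; neuron; glia; pluripotency; mesoderm and endoderm; neural crest and mesenchyme; non-neural ectoderm and epithelium; proliferation; p53 and stress response; interferon response and MHC class I; imprinted genes; genes with known strain differences; and Y-linked. Of 277 members 270 were found, and the 7 not listed (H19, Meg3, Rian, Mirg, Kcnq1ot1, Airn and Peg13) are imprinted genes. Lists were tested with camera in limma 3.58.1 (inter-gene correlation 0.01, Benjamini-Hochberg over 102 tests); 14 of these were called, and 0 with an estimated correlation. List scores over outbred lines were means of log2(CPM + 1) after each gene was centred and divided by its SD, compared by Pearson and Spearman correlation with 100000 permutations.

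The named genes were Pax6, Sox1, Sox2, Nes, Emx2, Nkx2-1 and Pou5f1 in every comparison. To these came the 6 largest positive and 6 largest negative log2 fold changes among called genes of at least 10 mean CPM in the higher group, without predicted genes, RIKEN clones, pseudogenes and Y-linked genes. From each list came up to 4 called members with the lowest adjusted p, or else its member of the highest level. For F-tests and spread the 10 genes with the lowest p or largest SD were named. Other genes (among them Pgam1-ps2, Ddx3y, Gm10222, Gm10925, Gm28661, Lars2, Rplp1, Top1, Utf1, Fgf5, Epcam and the copies of named genes) were chosen after their values were seen. Sequence sharing was the percentage of a gene's 31-base sequences found in transcripts of other genes.

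The alternatives were DESeq2 1.42.0, DESeq2 size factors, no count filter, length offsets, no genes on X and Y, leaving out libraries, strains or series, other measures and thresholds, and for list scores a pseudocount of 0.1. Those chosen after the data had been seen were protein-coding genes alone, genes of identical or equal-length models, the kinds of library (divided at Pgam1-ps2 present or absent), CAST/EiJ 1 left out, the 5 libraries with fewer than 50000 transcripts left out, and other centring of chromosomes. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The differential tests were run on simulated data with 200 changed genes, and the other tests on simulations of their own. In the simulated counts all genes had the same coefficient of variation, 0.3 for founder lines and 0.5 where outbred lines were included. The common value in the real data was 0.376 for the founder fit and 0.566 for outbred against founder lines, so recovery there can be lower. At 8-fold the differential tests recovered 82.8% in the founder F-test and 98.5, 98.5 and 100% for CAST/EiJ, PWK/PhJ and NZO/HiLtJ. For NOD/ShiLtJ and for WSB/EiJ it was 90.6%, for outbred against founder lines 100% and for the title series 89.2%. At 2-fold these were 9.38, 10.4, 9.09, 3.08, 3.08, 4.62, 59.1 and 24.2%. Of the simulated calls 1.85, 5.04, 6.72, 4.27, 8.25, 1.18, 7.39 and 2.10% were false, so 5% was exceeded for CAST/EiJ, PWK/PhJ, NOD/ShiLtJ and the outbred comparison. No library was left out of the main results and none was a copy of another. Intervals and floors cover counting error alone. Counts that coincide with a line number were given to 2 digits. The results for some genes are not reported here. Reads were not used here.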

Results

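RNA abundance was measured in 72 cultures of mouse neural progenitor cells, the dividing precursors of neurons and glia. Each culture was differentiated from epiblast stem cells towards telencephalic identity, the identity of the anterior brain from which cortex and basal ganglia form, and was collected at passage 2. The 10 founder libraries came from 6 inbred strains, with 2 lines each of C57BL/6J, CAST/EiJ, NZO/HiLtJ and PWK/PhJ and 1 line each of NOD/ShiLtJ and WSB/EiJ. The other 62 libraries came from Diversity Outbred lines, each from a stock in which the genomes of several founder strains are mixed. The 6 strains measured here need not be all of these founders. The titles number these lines by series, with 5, 12, 15, 14, 13 and 3 lines in the 100 to 600 series. The estimated fragment counts of a library summed to between 1.50e+07 and 3.51e+07 (median 2.21e+07), and to between 1.73e+07 and 3.28e+07 in the founders. Between 12585 and 13706 genes reached 1 count per 1e+06 counts (CPM) in a library. Below, values after ± are standard deviations (SD) for CPM and standard errors for log2 fold changes. The p-values of differential tests of single genes measure the spread between lines. Those of camera and of Fisher's exact test weigh genes against other genes, which are not independent.

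Telencephalic and progenitor genes were present in both kinds of line. Nes, an intermediate filament of neural progenitors, stood at 873 ± 276 CPM in the outbred lines (n = 62) and 844 ± 271 CPM in the founders (n = 10), and the progenitor factor Sox2 at 136 ± 43.2 and 165 ± 31.8 CPM. Sox1 had 101 ± 50.1 and 110.2 ± 56.9 CPM, Pax6 16.6 ± 8.75 and 16.5 ± 6.09 CPM, and Emx2 11.1 ± 4.36 and 10.3 ± 4.13 CPM. The pluripotency factor Pou5f1 did not exceed 0.104 CPM in any outbred line or 0.135 CPM in 9 founder libraries, and stood at 298 CPM in CAST/EiJ 1. The outbred libraries fell into sets on the pseudogene Pgam1-ps2, which had 22.1 to 73.1 CPM in 25 libraries, called the first kind below, and 0 in 37, the second kind. The founder libraries had 24.0 to 46.9 CPM. Between these kinds, 8268 of 15812 genes differed (4485 higher and 3783 lower).

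The first comparison asked which genes differed between the 6 founder strains. Lgals1, which encodes the lectin galectin-1 (chromosome 15: 78926725 to 78930465), was nearly missing from PWK/PhJ, with 0.856 ± 0.133 CPM (n = 2) against 869.7 ± 149.95 CPM in C57BL/6J (n = 2) and 1058 ± 77.6 CPM in NZO/HiLtJ (n = 2). The ribosomal protein gene Rpl26 (11: 68901583 to 68906989) stood at 22.7 ± 1.13 CPM in NZO/HiLtJ and between 291 and 504 CPM in the other strain means, and Rpl37a at 21.4 ± 1.92 CPM in PWK/PhJ and between 297 and 351 CPM elsewhere. The chromatin protein gene Hmgn2 (4: 133964738 to 133968650) had 899 ± 12.4 CPM in C57BL/6J, 625.1 CPM in NZO/HiLtJ and 166 to 184 CPM in the other 4 strains. The glycolytic gene Gapdh (6: 125161715 to 125166467) had 1715 ± 29.0 CPM in C57BL/6J, 12.3 ± 2.74 CPM in PWK/PhJ, 16.4 CPM in WSB/EiJ and 28.9 ± 20.4 CPM in CAST/EiJ, and 727 and 659.8 CPM in NOD/ShiLtJ and NZO/HiLtJ.

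The F-test over the 6 strain means called 249 of 16057 genes (adjusted p below 0.05), and 2622 passed unadjusted. Among named genes the lowest adjusted p was that of the mitochondrial gene mt-Nd4l (F = 221.9, adjusted p = 0.00161), followed by Lgals1 (F = 103, 0.00209), Hmgn2 (F = 95.3, 0.00235), Rpl26 (F = 91.4, 0.00244) and Rpl37a (F = 89.7, 0.00249). Next came Rpl35a (F = 79.1, 0.00300), Eno1b (F = 64.7, 0.00428), Tpm3-rs7 (F = 61.7, 0.00478), Erh (F = 59.4, 0.00531) and Gapdh (F = 55.9, 0.00627). Many of these genes share sequence with near-identical copies, and their levels are uncertain for that reason. Other genes also held 98.9% of the 31-base sequences of mt-Nd4l, 89.2% of those of Eno1b, 78.6% of Tpm3-rs7, 43.0% of Erh, 29.8% of Hmgn2, 28.1% of Gapdh and 27.1% of Rpl26, but 0% of those of Lgals1. Summed over Gapdh and its 12 closest copies the level was 1994 CPM in C57BL/6J, 2965 CPM in CAST/EiJ, 1385 CPM in PWK/PhJ and 2020 CPM in WSB/EiJ, against 969, 324.2, 297 and 309.2 CPM for Hmgn2 with its 12 copies. Eno1 fell from 1188 CPM in C57BL/6J to between 21.2 CPM (PWK/PhJ) and 792 CPM in the other strains, where Eno1b appeared, and the sum over Eno1 and its 5 copies was 1188 CPM against 1263 to 2524 CPM. Tpm3 fell from 539.7 to between 110 and 147 CPM, and with Tpm3-rs7 the sum was 539.8 against 413 to 479 CPM. Rpl35a fell from 230 CPM in C57BL/6J to between 33.1 and 39.4 CPM in the other strains. Its 12 copies rose from 0.388 to between 62.8 and 68.5 CPM, and the sum was 230 against 95.9 to 107 CPM. The calls for Eno1b, Hmgn2, Rpl26, Rpl35a and mt-Nd4l held without any single library. Without PWK/PhJ 1 or PWK/PhJ 2 the adjusted p of Lgals1 was 0.0600 or 0.0594, of Rpl37a 0.0752 or 0.0814, of Tpm3-rs7 0.0600 or 0.0590, of Erh 0.108 or 0.123 and of Gapdh 0.0728 or 0.0749. The count was 156 without C57BL/6J 2, 667 and 1766 without CAST/EiJ 1 and 2, 75 and 69 without NZO/HiLtJ 1 and 2, and 34 and 33 without PWK/PhJ 1 and 2.

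**Figure D1:**
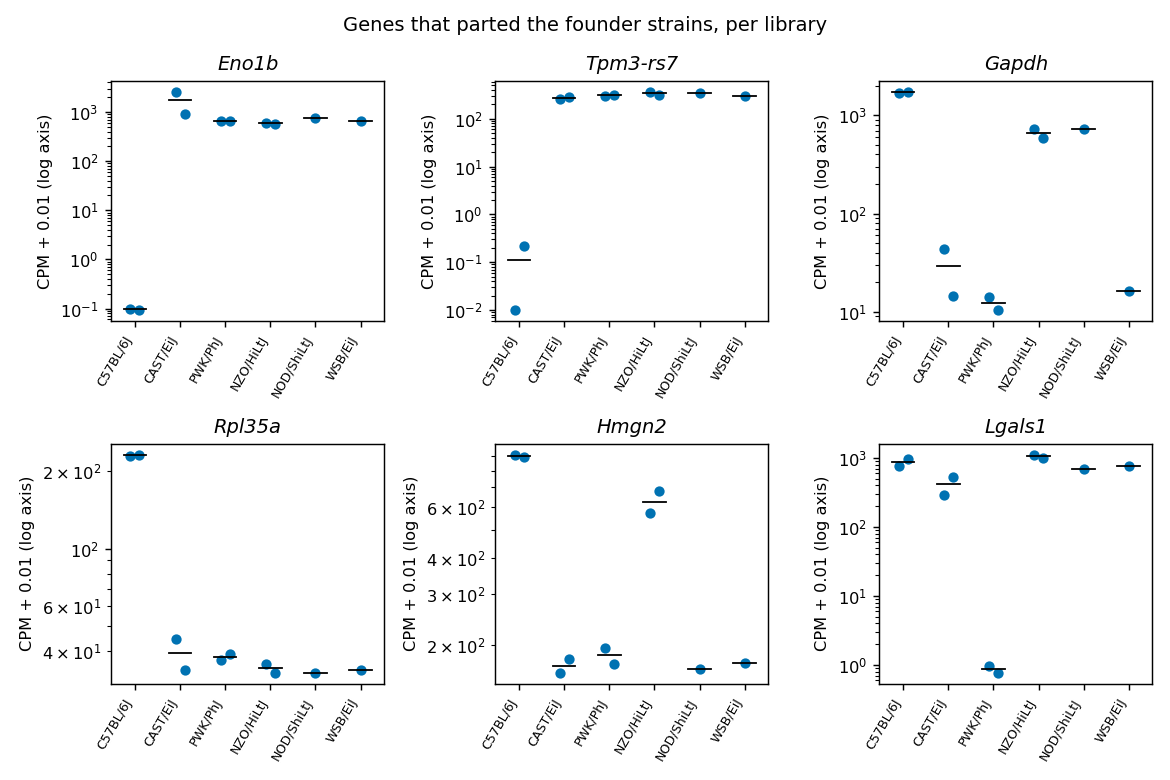
Each point is 1 founder library and each bar the mean of its strain, for 6 genes named in the text, as CPM on a logarithmic axis after adding 0.01. Gapdh spanned 12.3 to 1715 CPM and Lgals1 0.856 to 1058 CPM over the strain means, while Eno1b and Tpm3-rs7 were near 0 in C57BL/6J alone.

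CAST/EiJ, a wild-derived strain, was compared with C57BL/6J, the strain of the reference genome (2 lines against 2). Mtus1, a microtubule-associated gene (8: 40990914 to 41133726), rose to 35.8 ± 4.26 CPM from 5.49 ± 1.95 CPM (log2 fold change 2.63 ± 0.28, adjusted p = 0.0113). The major histocompatibility complex class I gene H2-D1 (17: 35262730 to 35267499) fell to 1.03 ± 0.112 CPM from 13.3 ± 5.51 CPM (log2 fold change -3.75 ± 0.53, adjusted p = 0.0394). Other genes also held 26.9% of the 31-base sequences of H2-D1. Fam234b (6: 135197977 to 135244955) fell to 4.21 ± 0.223 CPM from 39.3 ± 10.8 CPM (log2 fold change -3.29 ± 0.41, adjusted p = 0.0233). Hmgn2 fell (log2 fold change -2.49 ± 0.17, adjusted p = 0.00188), as did Rpl35a (log2 fold change -2.62 ± 0.21, adjusted p = 0.00375) and Gapdh (log2 fold change -5.96 ± 0.58, adjusted p = 0.00749). The enolase copy Eno1b (18: 48045335 to 48048412) had 1731 ± 1167 CPM against 0.0865 ± 0.00466 CPM, and the tropomyosin copy Tpm3-rs7 (14: 113314608 to 113316754) 275 ± 21.5 CPM against 0.104 ± 0.147 CPM (adjusted p = 0.000737 and 0.00102). AK157302 had 23.9 ± 14.1 CPM and no counts in C57BL/6J, at least 184-fold higher (floor of 3 counts per library, adjusted p = 0.00719), and shared 75.7% of its 31-base sequences with other genes. The taste receptor gene Tas1r1 (log2 fold change 7.39 ± 0.95, adjusted p = 0.0249) and the RNA-binding gene Rbm12b1 (log2 fold change 2.69 ± 0.39, adjusted p = 0.0434) rose, and the NKG2D ligand gene Raet1d fell (log2 fold change -6.45 ± 0.94, adjusted p = 0.0434). Other genes also held 69.3% of the 31-base sequences of Rbm12b1 and 67.1% of those of Raet1d, so these levels are uncertain too.

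In all, 71 genes rose and 24 fell of 16057 in CAST/EiJ. With protein-coding genes alone 15 rose and 15 fell, and without CAST/EiJ 2 865 rose and 1013 fell. None of Pax6, Sox1, Sox2, Nes, Emx2 and Nkx2-1 was called. None of the 14 tested genes of the midbrain, hindbrain and spinal cord list passed over all genes, 5 were higher adjusted over the list alone, and camera called the list higher (adjusted p = 0.00918, and adjusted p = 0.711 with an estimated correlation). The 2 CAST/EiJ libraries differed in markers of other cell types. CAST/EiJ 1 had 1076 CPM of Lin28a and 295 CPM of Cdh1, and CAST/EiJ 2 had 0.0583 and 0.816 CPM. The calls for Eno1b, Tpm3-rs7, Gapdh, Rpl35a and Hmgn2 held without any single library. The adjusted p of AK157302 was 0.0512 and 0.0515 without PWK/PhJ 1 and 2, of Mtus1 up to 0.0722 (without C57BL/6J 2), of Fam234b up to 0.0910 (without C57BL/6J 2), of Raet1d up to 0.146 (without NZO/HiLtJ 2), of Tas1r1 and Rbm12b1 up to 0.213 (both without C57BL/6J 2) and of H2-D1 up to 0.126 (without PWK/PhJ 2). With transcript length offsets the adjusted p was 0.0639 for Mtus1, 0.0556 for H2-D1 and 0.225 for Rbm12b1. The count of 95 genes was 33 without C57BL/6J 2, 54 without NZO/HiLtJ 1 or 2, 35 without PWK/PhJ 1 or 2, and 1878 without CAST/EiJ 2.

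PWK/PhJ, also wild-derived, had 274 genes called against C57BL/6J (2 lines against 2). Col5a2, a fibrillar collagen gene of connective tissue (1: 45374321 to 45503282), rose to 440.3 ± 89.4 CPM from 2.32 ± 2.75 CPM (log2 fold change 7.52 ± 0.97, adjusted p = 0.0167). Lgals1 fell to 0.856 ± 0.133 CPM (log2 fold change -10.08 ± 0.46, adjusted p = 0.000241). Slc25a24, a mitochondrial carrier gene (3: 109123149 to 109168457), fell to 0.309 ± 0.101 CPM from 32.0 ± 4.35 CPM (log2 fold change -6.76 ± 0.94, adjusted p = 0.0218). Six6, a transcription factor of the eye field and anterior forebrain (12: 72939892 to 72944899), fell to 0.975 ± 0.371 CPM from 14.9 ± 0.955 CPM (log2 fold change -4.01 ± 0.61, adjusted p = 0.0279). It was the member called among 12 tested telencephalon genes, both over all genes and adjusted over the list alone. Arhgap45 rose from 0.0449 ± 0.0635 CPM, too few counts for a fold, to 38.7 ± 2.88 CPM (adjusted p = 0.0396), and Lgals3bp rose (log2 fold change 6.19 ± 0.93, adjusted p = 0.0275). H2-D1 fell (log2 fold change -3.91 ± 0.54, adjusted p = 0.0209), as did Gapdh (log2 fold change -7.22 ± 0.61, adjusted p = 0.00318). The histone gene Hist1h4i had 0.0476 CPM against 10.4 ± 5.40 CPM (adjusted p = 0.00453).

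Copies with shared sequence changed here as well. Eno1b had 657 ± 8.38 CPM, Tpm3-rs7 309.2 ± 13.8 CPM, and AK157302 21.9 ± 1.21 CPM with no counts in C57BL/6J, at least 169-fold higher (adjusted p = 0.000922, 0.000865 and 0.00538). The mitochondrial gene mt-Nd4l had no counts in PWK/PhJ and 181 ± 24.1 CPM in C57BL/6J, at least 1266-fold lower (adjusted p = 0.000241), while its near-identical nuclear copy Gm10222 was present in PWK/PhJ alone among the founders, and mt-Co2 had 6.82 ± 4.87 against 3447 ± 550.1 CPM (adjusted p = 0.0231). In all, 153 genes rose and 121 fell, and with protein-coding genes alone 48 rose and 86 fell. None of the 16 proliferation genes was called over all genes, 3 were lower adjusted over the list alone, and camera called the list lower (adjusted p = 0.00445, and adjusted p = 0.853 with an estimated correlation). Camera called the neural crest and mesenchyme list higher (adjusted p = 0.00918, and adjusted p = 0.853 with an estimated correlation), with 0 of 16 members called over all genes or adjusted over the list alone. Eno1b, Tpm3-rs7, mt-Nd4l and Lgals1 held without any single library. The adjusted p of AK157302 was 0.0553 without PWK/PhJ 2. Without PWK/PhJ 1 or 2 it was 0.0605 or 0.0743 for Gapdh, 0.0908 or 0.0980 for Hist1h4i, 0.0982 or 0.132 for Col5a2, 0.208 or 0.274 for Slc25a24, 0.250 or 0.233 for Six6, 0.216 or 0.214 for H2-D1, 0.178 or 0.264 for mt-Co2, 0.178 or 0.227 for Arhgap45 and 0.0982 or 0.209 for Lgals3bp. The count of 274 was 178 and 77 without C57BL/6J 1 and 2, 756 and 746 without CAST/EiJ 1 and 2, 129 without NZO/HiLtJ 1 or 2, and 47 and 38 without PWK/PhJ 1 and 2.

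NZO/HiLtJ, an inbred strain used as a model of obesity, had 22 genes that rose and 13 that fell against C57BL/6J (2 lines against 2), and 6 and 9 with protein-coding genes alone. The formin gene Inf2 (12: 112588784 to 112615557) rose to 117 ± 16.0 CPM from 18.2 ± 5.38 CPM (log2 fold change 2.74 ± 0.34, adjusted p = 0.0433). Mtus1 rose to 42.6 ± 1.79 CPM (log2 fold change 3.01 ± 0.28, adjusted p = 0.0122). Nxph1, a secreted ligand of neurexins (6: 8948431 to 9249032), fell to 0.361 ± 0.0987 CPM from 13.8 ± 3.13 CPM (log2 fold change -5.23 ± 0.51, adjusted p = 0.0143). Rpl26 fell (log2 fold change -4.19 ± 0.21, adjusted p = 0.000566), as did Fam234b (log2 fold change -3.84 ± 0.42, adjusted p = 0.0238) and Rpl35a (log2 fold change -2.70 ± 0.21, adjusted p = 0.00527). Phgdh, the first enzyme of serine synthesis (55.5% of 31-base sequences shared), fell to 50.6 ± 13.3 CPM from 265 ± 6.18 CPM (log2 fold change -2.34 ± 0.26, adjusted p = 0.0242), and Rapgef3 rose (log2 fold change 1.92 ± 0.24, adjusted p = 0.0418). Eno1b had 586 ± 26.2 CPM and Tpm3-rs7 339 ± 36.8 CPM (adjusted p = 0.00134 and 0.00120). The extracellular matrix gene Tnc, named as the glial member with the highest level, had 2078 ± 622 against 214.98 ± 151 CPM and was not called (log2 fold change 3.35 ± 0.64, adjusted p = 0.137).

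In NZO/HiLtJ none of the members of the 17 gene lists passed over all genes. Camera called neural crest and mesenchyme genes higher (adjusted p = 0.00756, and adjusted p = 0.853 with an estimated correlation), and 6 of its 16 members were higher adjusted over the list alone. It called proliferation genes (adjusted p = 0.0188) and dorsal telencephalon genes (adjusted p = 0.0153) lower, both with an adjusted p = 0.853 with an estimated correlation. The reference libraries C57BL/6J 1 and 2 stood apart on the dorsal telencephalon score (1.08 and -0.336), with NZO/HiLtJ 1 and 2 at -0.611 and -0.631. They also differed in the neuron score (0.991 and -0.682 in C57BL/6J 1 and 2). The calls for Eno1b, Tpm3-rs7 and Rpl26 held without any single library. Without NZO/HiLtJ 1 or 2 the adjusted p was 0.0926 or 0.107 for Rpl35a, 0.330 or 0.186 for Inf2, 0.140 or 0.119 for Mtus1, 0.272 or 0.185 for Nxph1, 0.247 or 0.119 for Fam234b, 0.102 or 0.183 for Phgdh and 0.376 or 0.188 for Rapgef3. The length offsets gave Mtus1 0.0870, Inf2 0.0598 and Rapgef3 0.242. The count of 35 was 69 and 19 without C57BL/6J 1 and 2, 175 and 174 without CAST/EiJ 1 and 2, 11 without NZO/HiLtJ 1 or 2, and 19 and 20 without PWK/PhJ 1 and 2.

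The single NOD/ShiLtJ line, of a strain that develops autoimmune diabetes, had 19 genes that rose and 9 that fell (5 and 7 with protein-coding genes alone); its spread was taken from the other strains. The ribosomal protein gene Rpl30 fell to 57.6 CPM from 351 ± 31.8 CPM (log2 fold change -2.62 ± 0.30, adjusted p = 0.0315), and Rsph3b, a gene of the radial spokes of cilia (75.6% shared), fell to 1.32 CPM from 22.0 ± 0.297 CPM (log2 fold change -4.06 ± 0.37, adjusted p = 0.0145). Rpl35a fell (log2 fold change -2.80 ± 0.28, adjusted p = 0.0209), as did Hmgn2 (log2 fold change -2.44 ± 0.22, adjusted p = 0.0145). The tropomyosin gene Tpm3 fell to 124 CPM from 539.7 ± 12.0 CPM (log2 fold change -2.13 ± 0.26, adjusted p = 0.0477), while its copy Tpm3-rs7 had 355 CPM (adjusted p = 0.00196); with length offsets Tpm3 was at -0.23 and not called. Eno1b had 769 CPM (adjusted p = 0.00196). Interferon response and MHC class I genes had the lowest camera p of all lists here (higher, adjusted p = 4.82e-05, and adjusted p = 0.711 with an estimated correlation). Of 15 members 12 had positive log2 fold changes (median 1.38), 0 passed over all genes and 2 were higher adjusted over the list alone. B2m, the light chain of class I molecules, had 90.2 against 44.3 ± 2.87 CPM (log2 fold change 1.02 ± 0.33, adjusted p = 0.713). Camera also called the midbrain, hindbrain and spinal cord list (adjusted p = 0.0191, and 0.711 as adjusted p with an estimated correlation) and the neural crest and mesenchyme list (adjusted p = 0.00445, and 0.853) higher.

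Tpm3-rs7 held without any single library of the 9 that could be left out, and Eno1b had an adjusted p of 0.0551 without C57BL/6J 2. The adjusted p was up to 0.0967 for Rsph3b and Hmgn2 and up to 0.201 for Tpm3 (each without PWK/PhJ 1), up to 0.143 for Rpl30 (without PWK/PhJ 2) and up to 0.104 for Rpl35a (without C57BL/6J 2). The NOD/ShiLtJ count of 28 was 6 without C57BL/6J 2, 70 without CAST/EiJ 1 or 2, 14 without NZO/HiLtJ 1 or 2 and 8 without PWK/PhJ 1 or 2.

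The single WSB/EiJ line, of another wild-derived strain, had 38 genes that rose and 17 that fell (16 and 12 with protein-coding genes alone). Sox8, a transcription factor of glial precursors (17: 25565892 to 25570686), rose to 84.2 CPM from 1.93 ± 0.134 CPM (log2 fold change 5.42 ± 0.66, adjusted p = 0.0279). Aldh1l1, a folate enzyme that marks astrocytes (6: 90486427 to 90600203), rose to 14.4 CPM from 0.514 ± 0.156 CPM (log2 fold change 4.75 ± 0.65, adjusted p = 0.0484). The metabotropic glutamate receptor gene Grm5 (7: 87584168 to 88134907) rose to 57.6 CPM from 1.56 ± 0.0226 CPM (log2 fold change 5.18 ± 0.44, adjusted p = 0.00661), and the cell adhesion gene Chl1 (6: 103510586 to 103750211) to 77.9 CPM from 3.04 ± 1.42 CPM (log2 fold change 4.66 ± 0.51, adjusted p = 0.0187). Arhgef10 fell to 6.69 CPM from 43.0 ± 4.18 CPM (log2 fold change -2.71 ± 0.31, adjusted p = 0.0225). Raet1e had no counts against 57.7 ± 37.6 CPM, at least 388-fold lower (adjusted p = 0.0253), with 55.2% of its 31-base sequences shared. Gapdh (log2 fold change -6.74 ± 0.82, adjusted p = 0.0279), Cyp4f16 (log2 fold change -5.51 ± 0.67, adjusted p = 0.0279), Rpl35a (log2 fold change -2.79 ± 0.28, adjusted p = 0.0138) and Hmgn2 (log2 fold change -2.41 ± 0.22, adjusted p = 0.00910) fell, but summed with its copies Gapdh did not. Cyp4f16 shared 26.7% of its 31-base sequences with other genes. Eno1b had 668 CPM and Tpm3-rs7 302.6 CPM (adjusted p = 0.00138 for both).

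Aldh1l1 was the 1 of 12 glial genes called in WSB/EiJ over all genes, 5 were higher adjusted over the list alone, and camera called the list higher (adjusted p = 0.00756, and adjusted p = 0.711 with an estimated correlation). The midbrain, hindbrain and spinal cord list (adjusted p = 0.00445, and 0.711 as adjusted p with an estimated correlation) and the ventral telencephalon list (adjusted p = 0.0168, and 0.853) were also called higher; without CAST/EiJ 1 the former had an adjusted p of 0.0511. Eno1b and Tpm3-rs7 held without any single library. The adjusted p of Grm5 was 0.0872 without C57BL/6J 2, and the highest was 0.229 for Sox8, 0.210 for Aldh1l1, 0.108 for Chl1, 0.108 for Gapdh, 0.110 for Cyp4f16, 0.0766 for Rpl35a and 0.0625 for Hmgn2 (all without C57BL/6J 2), 0.0980 for Arhgef10 and 0.0936 for Raet1e (both without PWK/PhJ 1). With length offsets the adjusted p was 0.0835 for Sox8, 0.334 for Aldh1l1 and 0.196 for Cyp4f16. The WSB/EiJ count of 55 was 22 without C57BL/6J 2, 127 and 121 without CAST/EiJ 1 and 2, 29 without NZO/HiLtJ 1 or 2, and 21 and 23 without PWK/PhJ 1 and 2.

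Outside these, the list members that passed over all genes in the strain contrasts were H2-D1 in CAST/EiJ and in PWK/PhJ, each 1 of 15 interferon and MHC class I genes. Adjusted over the list alone, genes with known strain differences had 3 members higher and 4 lower of 8 in PWK/PhJ and 1 higher in CAST/EiJ. In WSB/EiJ 2 pan-neural progenitor genes and 1 gene each of the dorsal telencephalon, midbrain and neural crest lists were higher. In NZO/HiLtJ 1 imprinted gene was higher, 1 pan-neural progenitor gene was lower and 1 mesoderm and endoderm gene moved each way. In CAST/EiJ 1 telencephalon gene was lower. Glial genes had 1 member higher in CAST/EiJ, 2 higher and 1 lower in PWK/PhJ, 1 higher and 2 lower in NZO/HiLtJ, and 2 higher in NOD/ShiLtJ. Interferon and MHC class I genes had 1 higher and 1 lower in CAST/EiJ, 1 lower in PWK/PhJ, 1 higher and 2 lower in NZO/HiLtJ, and 1 lower in WSB/EiJ. Neuron genes had 1 member higher in CAST/EiJ, PWK/PhJ and NZO/HiLtJ and 1 lower in PWK/PhJ. The pluripotency, non-neural ectoderm, p53 and stress, and Y-linked lists had 0 members called in any of the 5 contrasts, also adjusted over the list alone.

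On average, lines of 1 strain resembled each other more than lines of different strains over all genes. The mean Spearman correlation of log2 CPM was 0.965 within a strain and 0.938 between strains, a difference of 0.0272 (1-sided permutation test, p = 0.00607; exact p = 0.00614 over 4725 arrangements of the 10 libraries). Without PWK/PhJ the difference was 0.0177 (exact permutation p = 0.0643), and without CAST/EiJ 2 it was 0.0435 (exact permutation p = 0.000794). The pairs of NZO/HiLtJ and PWK/PhJ lines had correlations of 0.985 and 0.987. The C57BL/6J pair had 0.962, beside 0.961 for C57BL/6J 1 with NOD/ShiLtJ 1. The CAST/EiJ pair had 0.927, below the mean between strains. CAST/EiJ 2 was nearest to WSB/EiJ 1, with a correlation of 0.974.

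The next comparison set the 62 outbred lines against the 10 founder lines. Of 23 genes on the midbrain, hindbrain and spinal cord list 6 were higher in the outbred lines and 0 lower. En1, a homeobox gene of the midbrain-hindbrain boundary (1: 120602418 to 120607992), rose to 60.2 ± 51.3 CPM from 14.5 ± 14.7 CPM (log2 fold change 2.12 ± 0.49, adjusted p = 0.00412). Its relative En2 rose to 154 ± 95.8 from 56.7 ± 51.2 CPM (log2 fold change 1.49 ± 0.40, adjusted p = 0.0132), Pax5 (4: 44524757 to 44710487) to 30.1 ± 46.9 from 4.12 ± 5.90 CPM (log2 fold change 2.95 ± 0.85, adjusted p = 0.0193), and Lmx1b (2: 33560965 to 33640511) to 12.8 ± 10.3 from 3.94 ± 2.94 CPM (log2 fold change 1.76 ± 0.50, adjusted p = 0.0183). On this list 7 were higher adjusted over the list alone, 18 had positive log2 fold changes and the median was 1.49. Camera called the list higher (adjusted p = 0.00918, and adjusted p = 0.719 with an estimated correlation), but 52 of 100 splits of the 72 libraries gave as many called lists as the 2 found here, so chance was not excluded. Lhx2, a homeobox gene of the forebrain (2: 38339281 to 38369733), fell to 6.06 ± 6.21 from 21.2 ± 22.2 CPM (log2 fold change -1.76 ± 0.40, adjusted p = 0.00321) and was the 1 of 14 telencephalon genes called. Adjusted over the list alone, 1 telencephalon gene was higher and 1 lower. The ventral genes Dlx5 (0.190 ± 0.237 against 1.01 ± 1.58 CPM, log2 fold change -2.36 ± 0.52, adjusted p = 0.00249) and Dlx6 (log2 fold change -1.39 ± 0.38, adjusted p = 0.0136) fell, 2 of 14 on their list and 3 adjusted over the list alone. Nkx2-1, the factor of the medial ganglionic eminence, had 8.38 ± 14.8 against 30.5 ± 35.6 CPM (log2 fold change -1.83 ± 0.65, adjusted p = 0.0528). The dorsal gene Gli3 rose (221.7 ± 97.6 against 131 ± 46.1 CPM, log2 fold change 0.82 ± 0.21, adjusted p = 0.00941), 1 of 14 on its list.

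Of 16 proliferation genes 4 were higher in the outbred lines. The spindle checkpoint kinase gene Bub1 (2: 127801122 to 127831865) rose to 143 ± 29.4 from 50.4 ± 6.40 CPM (log2 fold change 1.57 ± 0.12, adjusted p = 1.34e-17), with transcript models that differed between the founder and outbred tables. Ccna2 (log2 fold change 0.48 ± 0.13, adjusted p = 0.0125), Mki67 (log2 fold change 0.55 ± 0.17, adjusted p = 0.0295) and Top2a (log2 fold change 0.36 ± 0.11, adjusted p = 0.0284) rose too, and none of these 3 was called with outbred libraries of the first kind. Adjusted over the list alone 4 were higher, and camera called the list higher (adjusted p = 0.0296, and adjusted p = 0.853 with an estimated correlation). With outbred libraries of the first kind camera, at its preset correlation, still called this list and the midbrain, hindbrain and spinal cord list. The lists called in the strain contrasts were not retested by this, because those contrasts hold no outbred libraries. Cxcr4, a chemokine receptor gene (1: 128588199 to 128592293), rose to 56.9 ± 22.1 from 28.0 ± 12.8 CPM (log2 fold change 1.08 ± 0.21, adjusted p = 0.000275), the 1 of 8 mesoderm and endoderm genes called, with 2 higher adjusted over the list alone. Among 16 neural crest and mesenchyme genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). Pax3 (log2 fold change 1.85 ± 0.45, adjusted p = 0.00603), Pax7 (log2 fold change 2.45 ± 0.65, adjusted p = 0.0116) and Tfap2b (log2 fold change 1.86 ± 0.58, adjusted p = 0.0291) rose, and Tfap2a fell (log2 fold change -1.27 ± 0.32, adjusted p = 0.00814). The cholesterol synthesis gene Idi1 (13: 8885501 to 8892451) rose to 263 ± 83.7 from 21.0 ± 4.59 CPM (log2 fold change 3.72 ± 0.21, adjusted p = 6.23e-25), and Psg16 (7: 17074040 to 17133450) to 25.0 ± 9.70 from 4.41 ± 1.28 CPM (log2 fold change 2.57 ± 0.22, adjusted p = 3.21e-15).

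Other lists had few members called. The apoptosis genes Bax (87.7 ± 47.7 against 156 ± 18.7 CPM, log2 fold change -0.79 ± 0.23, adjusted p = 0.0220) and Bbc3 (log2 fold change -0.87 ± 0.23, adjusted p = 0.0107) fell among 14 p53 and stress genes. The antigen-processing genes Tap1 (log2 fold change -0.58 ± 0.20, adjusted p = 0.0477) and Psmb9 (log2 fold change -1.07 ± 0.34, adjusted p = 0.0323) fell among 16 interferon and MHC genes, and Snrpn (log2 fold change -0.52 ± 0.17, adjusted p = 0.0389) and Rasgrf1 (log2 fold change -0.88 ± 0.30, adjusted p = 0.0417) among 22 imprinted genes. Each of these 3 lists also had 2 members lower adjusted over the list alone. Cdh2 (log2 fold change 0.35 ± 0.12, adjusted p = 0.0397) was the 1 of 15 progenitor genes and Elavl4 (log2 fold change 0.90 ± 0.31, adjusted p = 0.0496) the 1 of 19 neuron genes that rose, with 0 of either adjusted over the list alone and 0 of 12 glial genes by both counts. Glo1, a gene with known strain differences, rose (log2 fold change 0.55 ± 0.19, adjusted p = 0.0491), the 1 of 8 called, with 2 higher adjusted over the list alone. The Y-linked gene Kdm5d fell (log2 fold change -1.76 ± 0.42, adjusted p = 0.00509), 1 of 4 by both counts, and Ddx3y was at or below 1.87 CPM in 19 outbred lines and at 10.6 CPM or more in 43 outbred and all founder lines.

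The calls of some pluripotency and epithelial genes rested on CAST/EiJ 1. Lin28a (log2 fold change -4.36 ± 0.77, adjusted p = 5.66e-05), Zscan10 (log2 fold change -4.74 ± 0.49, adjusted p = 8.12e-12), L1td1 (log2 fold change -4.55 ± 0.50, adjusted p = 4.70e-11) and Cdh1 (log2 fold change -2.98 ± 0.58, adjusted p = 0.000368) fell. Without CAST/EiJ 1 their adjusted p was 0.151, 0.931, 0.921 and 0.686, and the log2 fold changes 2.52, -0.09, 0.11 and 0.48. Klf4 (log2 fold change -0.85 ± 0.20, adjusted p = 0.00349, and 0.00775 without CAST/EiJ 1) was the other of 2 pluripotency genes that fell of 7 tested, and Tfap2c (log2 fold change -1.52 ± 0.41, adjusted p = 0.0125) the other of 2 ectoderm genes of 9. Adjusted over the list alone, 1 pluripotency gene was higher and 3 lower, and 4 ectoderm genes were lower. Camera called neither list (adjusted p = 0.203 and 0.396). Without CAST/EiJ 1 the adjusted p was 0.289 for Tfap2c, 0.120 for Cdh2, 0.0857 for Elavl4, 0.0578 for Glo1, 0.220 for Psmb9, 0.0712 for Rasgrf1, 0.391 for Snrpn, 0.0735 for Tap1, 0.0529 for Tfap2b and 0.0474 for Nkx2-1. Tas1r1 fell (log2 fold change -3.84 ± 0.43, adjusted p = 1.59e-10), and without CAST/EiJ 1 was at -1.78 ± 0.45.

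A few large changes moved with the gene models. Zfp966 had 43.1 ± 31.6 CPM against no counts in the founders, at least 312.9-fold higher (floor of 3 counts per library, adjusted p = 8.47e-18), while Zfp969 fell (log2 fold change -5.49 ± 0.82, adjusted p = 8.64e-07) and Zfp965 rose (log2 fold change 2.73 ± 0.44, adjusted p = 5.67e-06). Summed over Zfp966 and its near-identical copies, the level was 99.9 ± 59.0 CPM in the outbred lines and 107 ± 89.5 CPM in the founders. Tmem254a fell (log2 fold change -3.40 ± 0.23, adjusted p = 8.93e-21), and with its copies Tmem254b and Tmem254c, listed for the outbred lines alone, the sum was 48.1 ± 29.0 against 60.2 ± 51.6 CPM. Unlike these, the DNA repair gene Tex15 had identical models in both sets of tables and no near-identical copies, and rose (log2 fold change 2.51 ± 0.71, adjusted p = 0.0186).

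In all, 1136 genes rose and 653 fell of 15987, and 4641 passed unadjusted. The balance moved with the fit: 925 rose and 105 fell with 1 mean per founder strain, 1187 and 1201 with no low-count filter, and 99 and 110 with library kind as a term. With 1 mean per strain 16 of 42 genes lost the call and 1 turned direction, and the adjusted p was 0.155 for Lhx2, 0.273 for Dlx5 and 0.174 for Dlx6. Of these genes 22 lost the call with kind as a term, 21 without NZO/HiLtJ, 16 without PWK/PhJ and 8 with length offsets, and without CAST/EiJ 12 lost it and 4 turned direction. The founder libraries carry the lowest library numbers, so that the kind of line cannot be told apart from any batch that follows these numbers. Against the 25 outbred libraries of the first kind alone, 282 genes were called and 168 of them were lower. Of the genes named, Idi1 (log2 fold change 3.53 ± 0.14, adjusted p = 1.25e-19), Psg16, Pax5 (adjusted p = 0.0247), En1 (0.00891), Lmx1b (0.000463), Lhx2 (0.00806), Cxcr4 (0.00721), Klf4 (0.0393), Tfap2a (0.0403), Bub1 and Kdm5d (0.0208) were called there too. Called no longer were En2 (adjusted p = 0.0706), Gli3 (0.0531), Tex15 (0.0582), Dlx6 (0.0866), Ccna2 (0.516), Top2a (0.605), Mki67 (0.862), Bax (0.462), Bbc3 (0.289), Tfap2c (0.0774), Tfap2b (0.139), Pax3 (0.134), Pax7 (0.144), Cdh2 (0.424), Elavl4 (0.348), Glo1 (0.101), Psmb9 (0.208), Tap1 (0.453), Snrpn (0.636) and Rasgrf1 (0.239). The count of 1789 was 1030 with 1 mean per founder strain, 1169 without C57BL/6J, 819 without CAST/EiJ, 739 without NZO/HiLtJ and 747 without PWK/PhJ.

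**Figure D2:**
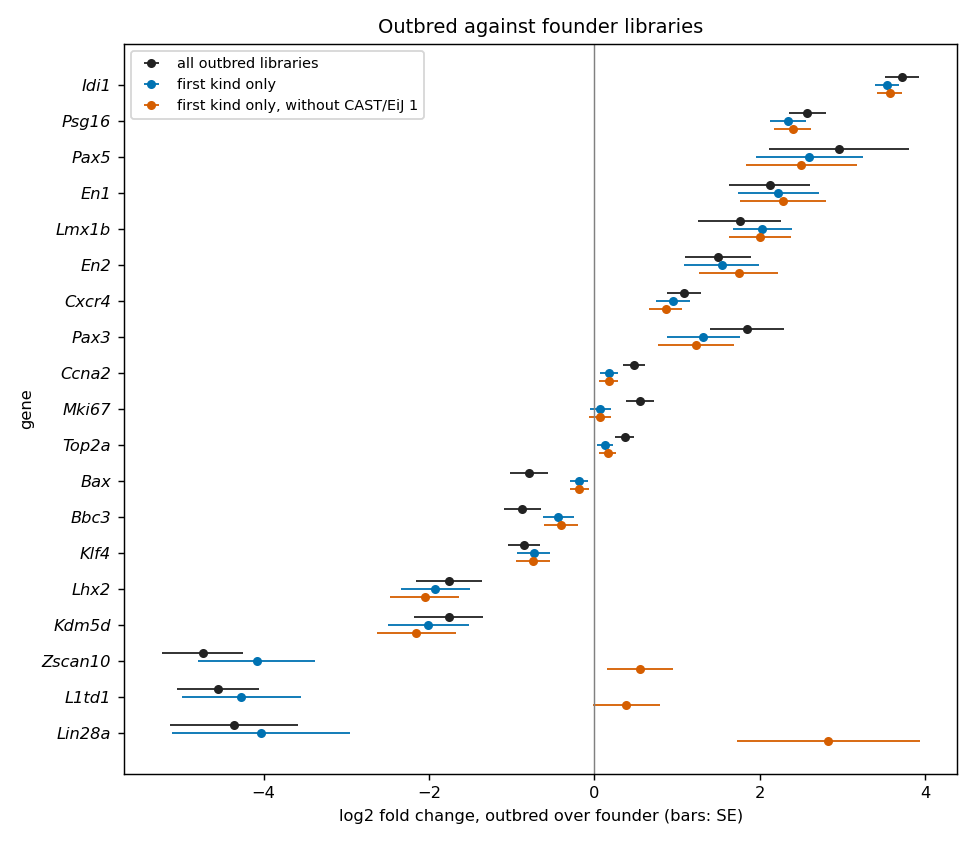
Points are log2 fold changes of outbred over founder lines and bars their standard errors for 19 named genes, from all 62 outbred libraries, from the 25 of the first kind, and from these without CAST/EiJ 1. En1 stood at 2.12 and 2.22 and Mki67 at 0.55 and 0.07 with all outbred libraries and with the first kind.

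**Figure D3:**
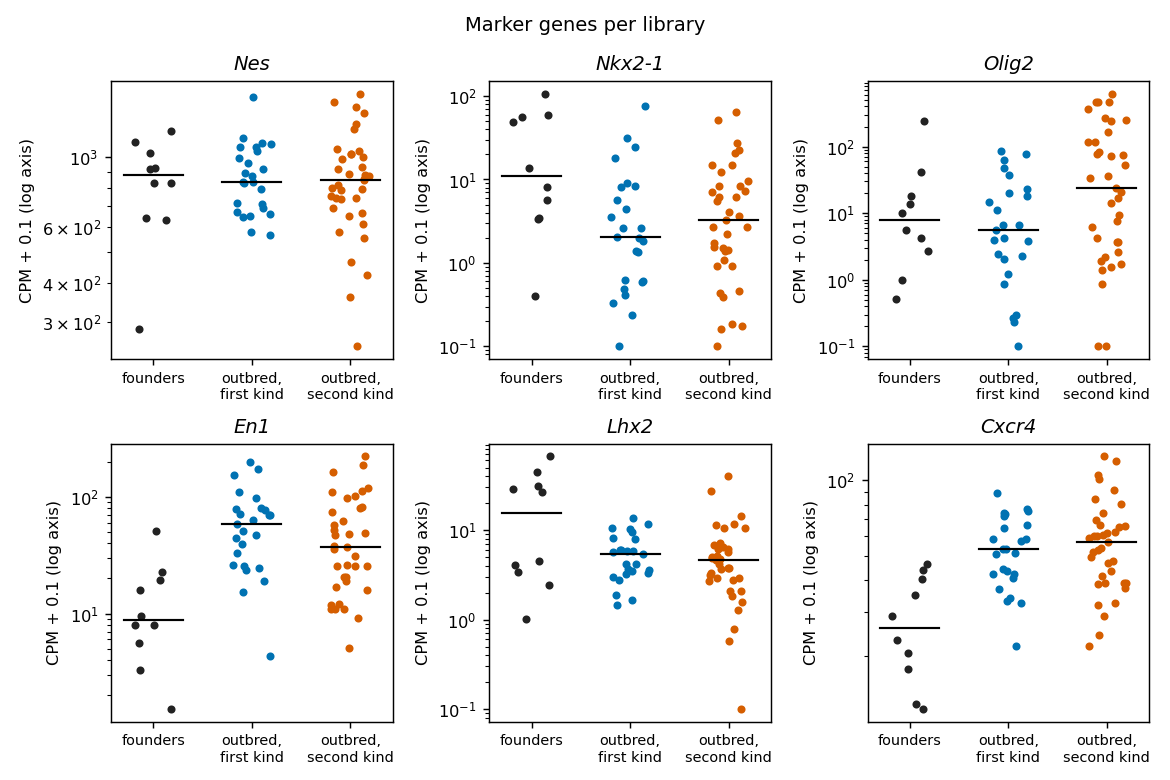
Each point is 1 library, as CPM on a logarithmic axis after adding 0.1, for Nes, Nkx2-1, Olig2, En1, Lhx2 and Cxcr4 in the 10 founders and in the 25 and 37 outbred libraries of the first and second kind, with lines at the medians. The Cxcr4 medians of both outbred kinds lay above that of the founders, and Olig2 spanned 0 to 623 CPM over the outbred lines.

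Outbred lines also differed among themselves. Olig1 and Olig2, transcription factors of oligodendrocyte precursors and of ventral progenitors, ranged from 0 to 1039 CPM (mean 113 ± 217) and from 0 to 623 CPM (mean 73.1 ± 137) over the 62 lines. The oligodendrocyte gene Bcas1 had 16.5 ± 40.8 CPM, the brain proteoglycan gene Bcan 129 ± 123 CPM, the astrocyte gene Sparcl1 125 ± 219.3 CPM (0 to 1037) and Cyp26b1, which degrades retinoic acid, 91.9 ± 173 CPM (0 to 828). These 6 and Tpm3-rs7 (0.0397 to 440.7 CPM), mt-Co2, mt-Nd4l and Rps3a1 (360.5 ± 335 CPM) had the largest SD of log2 values, from 2.16 for Rps3a1 to 3.21 for Tpm3-rs7. The common coefficient of variation was 0.548 among outbred lines and 0.369 between founder lines of a strain over 15397 genes, a ratio of 1.48. It was 1.86 without CAST/EiJ, 1.88 without CAST/EiJ 1 and 1.16 with outbred libraries of the first kind, but 1.47 with these and without CAST/EiJ 1. Across genes, which are not independent replicates, the spread between founder strain means and that over outbred lines went together (Spearman rho = 0.628, bootstrap SD 0.0288).

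The title series of the outbred lines were compared because the labels give that split, without saying what a series stands for. The F-test called 116 of 15812 genes (2615 unadjusted), and in each of the 10 genes named here the mean of the 3 lines of the 600 series was the highest. Tbpl1, a relative of the TATA-box binding protein, had 95.8 ± 22.1 CPM in the 600 series (n = 3) and 53.3 to 59.3 CPM in the other series means (F = 9.16, adjusted p = 0.00268). Fnbp1l had 353 ± 91.8 CPM against 203.1 to 238 CPM (F = 8.45, adjusted p = 0.00556), the ubiquitin ligase gene Rnf138 71.8 ± 23.2 against 44.1 to 54.9 CPM (F = 8.50, adjusted p = 0.00556), and the iron regulator Ireb2 345 ± 119 against 208 to 244 CPM (F = 7.87, adjusted p = 0.00911). The DNA damage kinase gene Atr had 96.7 ± 11.8 CPM and Fam126b 33.1 ± 10.7 CPM (adjusted p = 0.0121 for both), Mgea5 444.7 ± 87.9 CPM and Ero1lb 35.0 ± 11.1 CPM (0.0156 for both), and Cep97 50.5 ± 10.4 CPM and Nkap 54.6 ± 9.64 CPM (0.0198 for both). All 3 libraries of the 600 series were of the second kind. The count was 18 without the 600 series, 7 and 1 within the first and second kind (1100 and 1004 unadjusted), and 13 without the 5 libraries of lowest transcript number, of which ID_615 is in the 600 series. In each of these fits all 10 genes named lost the call. With length offsets the adjusted p was 0.130 for Tbpl1, 0.248 for Fam126b and 0.894 for Cep97, and with library kind as a term 4 of the 10 lost the call.

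Scores of the 17 lists were compared over the 62 outbred lines, in 136 pairs. Progenitor and proliferation genes went together (r = 0.668, rho = 0.556, both permutation p = 1e-05, adjusted p = 9.07e-05), and r was 0.528 without the 2 lines farthest from the median and 0.717 without the 5 libraries of lowest transcript number, which held 4 of the 6 lowest progenitor scores. The r was 0.737, 0.782, 0.707 and 0.582 within the 200 to 500 series, and 0.697 and 0.657 within the first and second kind of library. Telencephalon and glia scores went opposite ways (r = -0.651 with permutation p = 1e-05, rho = -0.538 with p = 2e-05, adjusted p = 9.07e-05), with r = -0.623 without 2 lines. Within series r was -0.611, -0.691, -0.725 and -0.522, and within the second kind -0.690; within the first kind it was -0.315 (adjusted p = 0.305) and the relation did not hold. Telencephalon and midbrain scores had r = -0.571 and rho = -0.579 (both permutation p = 1e-05, adjusted p = 9.07e-05), -0.528 without 2 lines, -0.367, -0.563, -0.824 and -0.538 within series, and -0.508 (adjusted p = 0.0581) and -0.513 within the first and second kind. Proliferation and interferon scores had r = -0.633 and rho = -0.544 (permutation p = 1e-05 and 2e-05, adjusted p = 9.07e-05), -0.592 without 2 lines, -0.863, -0.761, -0.562 and -0.484 within series, and -0.750 and -0.552 within kinds. The 100 and 600 series held too few lines for a value. Of the 136 pairs 57 were called, 33 of them with positive r, and 15 had p = 1e-05, the smallest that 100000 permutations can give (2-sided). Within the first kind 21 pairs were called, 16 of them shared.

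**Figure D4:**
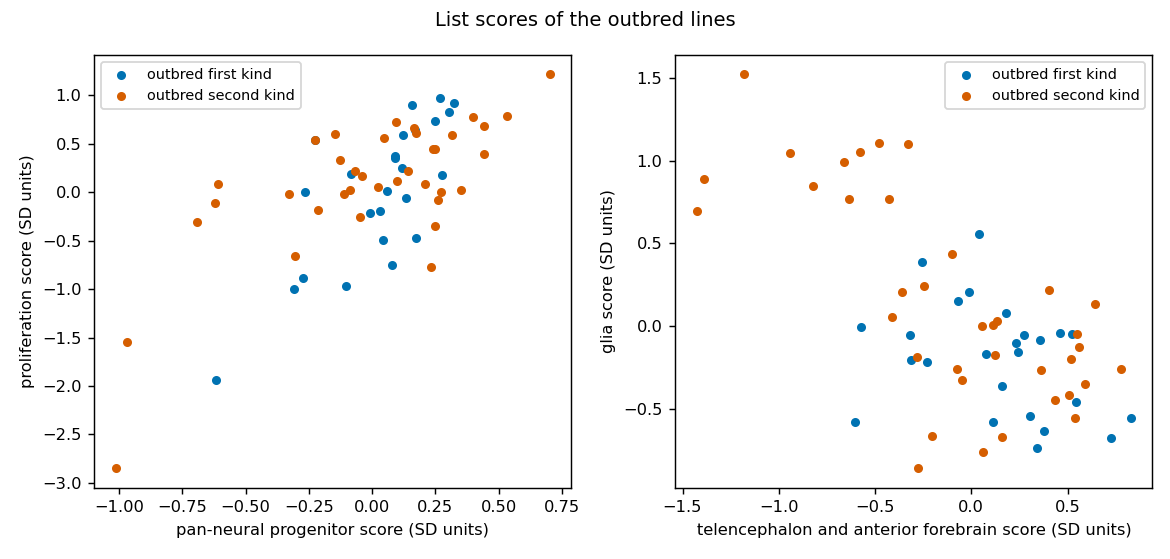
Each point is 1 of 62 outbred lines, coloured by kind of library, with the pan-neural progenitor score against the proliferation score and the telencephalon score against the glia score (mean standardised log2 values, no unit). The first pair rose together (r = 0.668) and the second went opposite ways (r = -0.651, and -0.315 in the first kind).

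Whole-chromosome shifts were sought because stem cell lines can gain chromosomes in culture. Of 1440 pairs of line and chromosome, 2 lay more than 0.3 above the gene medians in log2 units. In line ID_111 chromosome 16 was at 0.42, and in line ID_216 chromosome 6 was at 0.38. With genes centred within the kind of library both were at 0.40, a ratio of 1.32. The other 12 pairs lay below and came from lines ID_102, ID_516 and ID_615, which were among the 5 libraries of lowest transcript number; without these 5 the count was 2. Mitochondrial genes took the PWK/PhJ pattern in 5 outbred lines, with mt-Nd4l at or below 15.7 CPM in these and in PWK/PhJ and at 103 CPM or more in the other 65 libraries. Its near-identical copy Gm10222 had 159 to 962 CPM in the former and 0 in the latter, so that these values can reflect which copy the reads were assigned to.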

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

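All tests of explanations given here were chosen only after the results were seen. The single libraries below were found by asking whether the highest or lowest of 4 to 10 libraries lay far from its neighbour (Dixon's ratio of that gap to the whole range), which chance alone gives in about 1 in 20 groups; 6 of 60 groups and measures tested did so.

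CAST/EiJ 1 lay far above the other 9 founder libraries in Pou5f1 (298 against at most 0.135 CPM, ratio 1.00), in the pluripotency score (ratio 0.671) and in the non-neural ectoderm and epithelium score (ratio 0.655). It also had 1076 CPM of Lin28a, 295 CPM of Cdh1, 159 CPM of Utf1 and 42.8 CPM of Fgf5. NOD/ShiLtJ 1 had the highest total count of the founders, 3.28e+07 against 2.42e+07 for the next (ratio 0.555). In the 100 series of outbred lines, line ID_102 had the lowest number of transcripts, 30340 against 58222 for the next (ratio 0.865). Line ID_111 had the highest Nkx2-1 of that series, 51.7 against 9.44 CPM (ratio 0.817).

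The first pattern weighed was the 1789 genes called between outbred and founder lines. Chance was excluded for libraries taken as independent, since 1 of 100 splits, the real one, gave as many and the highest of the others gave 93. Lines of a strain resembled each other on average, which the splits ignore, and with 1 mean per strain the count was 1030 and 16 of 42 genes lost the call. With genes of identical models 91.7% of the calls stayed, which decides little, because 1705 of the 1789 had such models. Models that differ in a gene or in its near-identical copies touched 6.65% of the called genes and 3.17% of the others. This argues against such genes as the whole cause. Effects of the 2 annotations on all genes at once were not tested. The kinds of library among the outbred lines might account for part of the count. With the 25 libraries of the first kind 282 genes were called, and 20 random sets of 25 lines gave 247 to 3250 (median 1018). The test asked for fewer than in every random set and was not met. It cannot decide, because those sets held 10 to 18 lines of the second kind each. Their counts rose with that number (Spearman 0.843). The second kind alone gave 5682 genes, and kind as a term left 209. Of the 1789 genes 1375 also differed between the kinds, 1355 of them in the same direction, but the same outbred libraries enter both comparisons. This explanation stays open. A difference between the lines themselves also stays open, because the 282 calls exceeded the most from another split (137; 1 of 100 splits as large, so chance was excluded with the same limit), but library numbers follow the kind of line and the 2 cannot be told apart.

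The second pattern was that CAST/EiJ 2 held transcripts private to WSB/EiJ. With CAST/EiJ 2 set aside, 7 genes were on (10 CPM or more) in WSB/EiJ and off (under 1 CPM) in all other founder libraries. Of these, 5 were present in CAST/EiJ 2 (median level 0.543 of WSB/EiJ). Of 37 likewise private to CAST/EiJ 1, 20 were present in CAST/EiJ 2 (median 0.0816 of CAST/EiJ 1). The 37 include the pluripotency genes Pou5f1 and Utf1 (298 and 159 CPM in CAST/EiJ 1), so the other cell state of that library can have shaped this set. It can also have shaped the wider sets. At 72 genes off in CAST/EiJ 1 and on in WSB/EiJ the median level in CAST/EiJ 2 was 0.597 of WSB/EiJ. At 40 genes on in CAST/EiJ 1 and PWK/PhJ and off in WSB/EiJ the median level in CAST/EiJ 2 was 0.285 of CAST/EiJ 1. A library wholly from WSB/EiJ was excluded, because 95.0% of those 40 genes (38) reached 1 CPM in it. A line heterozygous for both strains stays open. It was set against 3 mitochondrial genes, which pass from the mother alone and lay at a median position of 0.702 between CAST/EiJ 1 (0) and WSB/EiJ (1); mt-Co1 had 286, 4599.7 and 7128 CPM in CAST/EiJ 1, CAST/EiJ 2 and WSB/EiJ. The nuclear copies Gm10925 and Gm28661 lay at 0.924 and 1 on that scale, near WSB/EiJ alone, and 3 others at 0.557 to 0.715. Material of both strains in 1 library also stays open. The shares of the wider sets add up to 0.883. Those of the private genes add up to less than the 0.7 that was required, a condition extended to them after their values were seen. That sum cannot decide, because pluripotency genes of CAST/EiJ 1 can lower the CAST/EiJ share whatever the origin of CAST/EiJ 2. The copy Gm28661 speaks against material of both strains.

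The third pattern was that pseudogenes made up 38.2% of the genes called between founder strains (95 of 249) and 5.27% of those tested (Fisher's exact p = 5.07e-57). Strain differences in transcription were argued against as the whole cause, because 96.8% of the called pseudogenes (92) were higher outside C57BL/6J, the reference strain, against 53.9% of other called genes (83 of 154). Reads of strain variants assigned to another near-identical copy stay open. The summed level of gene and copies varied less than 0.5 times as much in 43.2% of the called pseudogenes, all of which have copies, and in 37.7% of the other called genes that have copies (29 of 77; Fisher's exact p = 0.533). The other 77 called genes have no copy to exchange with. This comparison cannot decide, because the called genes with copies include Eno1b, Tpm3-rs7 and Gapdh, whose levels moved opposite to those of their copies. Among genes with copies that were not called the shares were 12.7% of 534 pseudogenes and 3.06% of 2905 others, which decide nothing, because called genes were chosen for their spread. For the other calls no biological explanation was tested.

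Splits of the lines into sets of the same sizes as the title series gave as many genes as the real 116 in 2 of 100 cases, the real one included. The highest other gave 194, so chance was not excluded, though so large a count was rare for lines taken as exchangeable. The splits ignored the kind of library, which is unevenly spread over the series, and within the kinds 7 and 1 genes were called, so a difference between kinds stays open. For the lists called between outbred and founder lines (2 by camera) chance was not excluded: 52 of 100 splits gave as many, and the highest other gave 7.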

How the results depend on the processing

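The alternatives with protein-coding genes alone, kinds of library, models, CAST/EiJ 1 and the low-complexity libraries were chosen only after the results were seen. No paired analysis was possible because the labels give line names, not shared replicate numbers. Where no cause is given below, the cause was not tested.

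With DESeq2 in place of edgeR the count of called genes was 2426 for the founder F-test, 617 for CAST/EiJ, 1155 for PWK/PhJ, 699 for NZO/HiLtJ, 2.2e+02 for NOD/ShiLtJ, 352 for WSB/EiJ and 697 for the title series. With no low-count filter these counts were 1303, 3.0e+02, 637, 3.1e+02, 82, 157 and 653. With protein-coding genes alone, which removes the pseudogenes, they were 97, 30, 134, 15, 12, 28 and 57. Leaving out 1 founder library at a time gave 33 to 1766 for the F-test, 33 to 1878 for CAST/EiJ, 38 to 756 for PWK/PhJ, 11 to 175 for NZO/HiLtJ, 6 to 70 for NOD/ShiLtJ and 21 to 127 for WSB/EiJ. A strain of 2 lines is then left with 1, assumed to vary like the others, and NOD/ShiLtJ or WSB/EiJ is left out wholly. All counts kept within 1.5 times under DESeq2 size factors, length offsets and without X and Y, except the title series.

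The count of 1789 between outbred and founder lines was 1030 with 1 mean per strain, 1169 without C57BL/6J, 819 without CAST/EiJ, 739 without NZO/HiLtJ and 747 without PWK/PhJ. It was 282 with outbred libraries of the first kind (186 of them shared), 281 with these and without CAST/EiJ 1, 5682 with the second kind, 209 with kind as a term and 1018 at the median of random sets of 25 lines. For the title series DESeq2 size factors gave 233, length offsets 77, no X and Y 66, no 600 series 18, no 100 series 77, no low-complexity libraries 13, the first kind 7, the second kind 1 and kind as a term 38.

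Founder similarity was 0.0177 without PWK/PhJ and 0.0435 without CAST/EiJ 2. The ratio of spread was 1.86 without CAST/EiJ, 1.88 without CAST/EiJ 1 and 1.16 with the first kind. The variability correlation was 0.593 with the interquartile range, 0.691 without the residual step, 0.716 with the first kind and 0.677 without low-complexity libraries. The first kind gave 21 called list pairs, and an estimated correlation 0 called lists. Chromosome shifts numbered 31 at 0.2, 2 at 0.4, 5 when centred within kind, 6 when centred per library, 2 with both and 2 without the low-complexity libraries.

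Of 2072 results for named genes under alternatives, 1603 kept direction and call, 8 gained the call, 17 turned direction, all between outbred and founder lines, and the rest lost the call. Zfp965 was at -0.12 with transcripts of equal length. With DESeq2 L1td1 was at 0.12, Lin28a at 1.25 and Cdh1 at 0.50, and Lin28a was at 2.49 with 1 mean per strain. Without CAST/EiJ L1td1 was at 0.39, Lin28a at 2.36, Cdh1 at 0.36 and Tas1r1 at 0.37; without CAST/EiJ 1 L1td1 was at 0.11, Lin28a at 2.52 and Cdh1 at 0.48. With the first kind and without CAST/EiJ 1 Zscan10 was at 0.55, L1td1 at 0.39, Lin28a at 2.82, Cdh1 at 0.75 and Snrpn at 0.0601.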

Other observations

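The pairs of lists were planned, and the pairs and markers described here, with the tests between kinds of library, were chosen only after the results were seen. Over the 62 outbred lines the scores of progenitor genes and of neural crest and mesenchyme genes went opposite ways (r = -0.606, rho = -0.627, adjusted p = 9.07e-05 over 136 pairs, both permutation p = 1e-05). The r was -0.569 without the 2 lines farthest from the median, -0.735, -0.671, -0.741 and -0.391 within the 200 to 500 series, and -0.746 and -0.568 within the first and second kind of library. Neural crest and interferon scores went together (r = 0.558, rho = 0.534, adjusted p = 9.07e-05), with r = 0.553 without 2 lines, 0.714, 0.530, 0.470 and 0.509 within series and 0.691 and 0.480 within kinds. Non-neural ectoderm and imprinted scores had r = 0.695 and rho = 0.720 (adjusted p = 9.07e-05), 0.710 without 2 lines, 0.666, 0.593, 0.843 and 0.793 within series, and 0.433 (adjusted p = 0.128) and 0.793 within kinds, so that the relation did not pass within the first kind.

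The kinds of outbred library differed in 8268 of 15812 genes, of which 3 are given as examples. The median of the ribosomal protein gene Rplp1 was 650.0 CPM in the founders, 599 CPM in the first kind (25 libraries) and 130 CPM in the second (37), that of Lars2 1193, 1031 and 125 CPM, and that of the topoisomerase gene Top1 238, 245 and 412 CPM. Over genes, which are not independent replicates, the change went with transcript length (Spearman 0.395). The median share of counts from mitochondrial genes was 2.54% in the first kind (at most 3.63%) and 4.05% in the second (at most 12.0%). Each of the 100 to 500 series held both kinds (1 and 4, 7 and 5, 5 and 10, 6 and 8, and 6 and 7 lines of the first and second), and the 600 series 3 lines of the second.

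Lines ID_102, ID_204, ID_320, ID_516 and ID_615, all of the second kind, had fewer than 50000 transcripts. Of 3286 weakly expressed genes, 9.56 to 47.2% had no counts in them, against 0.6999 to 8.09% in the other libraries, and mitochondrial genes took 7.47 to 12.0% of their counts and up to 9.43% in the others. Outbred lines ID_111 and ID_216 stood above the rest on chromosomes 16 and 6, at 0.42 and 0.38 in log2 units. With genes centred within kind both were at a ratio of 1.32, and both stayed above 0.3 with centring per library as well. Whether their chromosome numbers differ was not tested.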
